A study of Mus musculus with 2 samples.

How the data were processed

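Mitral valve leaflets of mouse embryos at E17.5, late in gestation, were measured by droplet-based single-cell RNA sequencing of 3′ ends. Per the labels, 3-4 hearts were pooled for each genotype, leaflets were digested with 0.05% trypsin, and cells that took up a viability dye were removed by sorting. There is 1 library from wild-type embryos (control) and 1 library from embryos that carry Nfatc1-Cre and loxP sites on both copies of Dicer1 (mutant). The deposited files hold raw UMI counts per gene and barcode, unit counts, made by the authors with Cell Ranger 5.0.0 on mm10 per the file headers and the submitters' processing notes. Both files list the same 32285 genes. The counting options, the annotation release and any barcode filter of the authors are not stated, and the smallest barcode total is 500 UMIs in each file.

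Barcodes were kept with at least 500 detected genes, at least 1000 UMIs and under 20% mitochondrial UMIs. Doublets were called in each library with the Scrublet method of scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes, and removed. In the control library 12793 barcodes with 70221728 UMIs gave 10347 kept cells, and in the mutant library 8250 barcodes with 69475632 UMIs gave 6190. The mitochondrial limit removed 11.4% of the control and 16.8% of the mutant barcodes. The doublet call took 3.83% of the control cells that passed the filters and 3.33% of the mutant ones, below the expected 8.61% and 5.12%, so doublets remain.

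Cells of both libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen as variable in each library, and 30 principal components, 15 exact nearest neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.8 followed. A cluster was called "-like" after a class of fixed marker genes when at least 3 markers were detected in at least 10% of its cells and at least 1.5-fold above the median of all clusters. It stayed unnamed when the next class came within 1 log2 of the best, when its 10 leading genes held more markers of another class, or when its UMI count was low and no leading gene was a marker. The marker genes were fixed before the data were examined. This scoring, with its lead of 1 log2, was set afterwards and left out of the classes clusters 4, 6, 9, 11, 13, 15, 18 and 23.

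Counts were summed per class and library and scaled by their total to CPM. The log2 ratio of mutant over control CPM, with 0.5 counts added, carries an exact conditional Poisson interval. CPM values carry exact Poisson and shares of cells exact Clopper-Pearson intervals, all at 95%. Every interval covers counting error only and not the spread between embryos or libraries. With 1 library per genotype no test between genotypes was made and no p-value is given. Genes with a mean CPM of at least 50 were counted when at least 2-fold apart. The fixed gene lists were summarised by the median log2 ratio of members with a mean CPM of at least 10, and by its percentile among 10000 random lists of the same size matched on mean CPM. A list was called outside the range of random lists below the 2.5th or above the 97.5th percentile, and lists with under 5 measured members got no percentile. Members count as higher or lower at 1.5-fold or more. In the files, 5 list symbols were not found.

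The genes named were set before the data were examined: in each of the 2 main classes, the 12 highest and the 12 lowest log2 ratios among genes with a mean CPM of at least 50. The higher CPM of such a gene had to reach its highest CPM in any named class of the same library, divided by 5, as a guard against free RNA. Erythroid, mitochondrial, ribosomal protein and sex-linked marker genes and unnamed predicted genes were left out. Dicer1, Nfatc1 and the up to 4 members with the largest absolute ratio of a described list were also named. Of the genes this rule names, 1 is not reported here. Other named genes are said to be so where they appear. A cell was called female-type when it held a UMI of Xist and none of Ddx3y, Eif2s3y, Kdm5d or Uty, male-type in the opposite case, and open otherwise.

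Coordinates come from GENCODE M21 on GRCm38, the assembly of mm10, in which 32235 of the 32285 gene identifiers were found. The 3′ UTRs used for seed sites were taken from the same annotation as the sequence after the coding region, and 44665 of 44675 were preceded by a stop codon. For seed sites, the mean log2 ratio of genes with and without each heptamer in the 3′ UTR was compared after a fit on UTR length, GC content and level was subtracted, and the site of each microRNA family was ranked among all heptamers. Between 97.1% and 97.7% of the genes tested in a class had an annotated 3′ UTR.

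Alternatives were a stricter filter (at least 1000 genes, 2000 UMIs, under 10% mitochondrial), no doublet removal, resolution 1.5, clustering without genes at least 2-fold apart between the whole libraries, a class per cell from its markers, ratios centred on the median gene, TMM factors from edgeR 4.0.16, the mean of per-cell CPM, lower level floors (10 CPM, and 5 for lists), cells thinned to 2000 UMIs, and other measures of cycling. Chosen after seeing the data were female-type cells alone, male-type mutant against female-type control cells, classes with further clusters added, equal cluster weights and the mean over all possible thinning draws. The calculation was tested on simulated data with known ratios: every gene set 4-fold up or down was found at least 2-fold apart in both classes, no unchanged gene was, and the shifted list stood at percentile 100. Genes set 2-fold up were found in 20.5% of cases in valve interstitial-like and 35.9% in endothelial-like cells. Genes set 2-fold down were found in 83.3% and 54.3%. A gene set at the limit itself can fall on either side of it, so these shares do not measure how complete the counts are. The simulated profile was rescaled to its total after the ratios were set, which shifted all of them. The difference between directions can therefore come from the simulation itself. In the same simulation 4 of 33 unshifted lists in valve interstitial-like and 1 of 31 in endothelial-like cells fell outside the range. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and R 4.3.3.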

Results

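The data are 2 single-cell libraries of mitral valve leaflets at E17.5, 1 from pooled wild-type hearts and 1 from pooled hearts in which Nfatc1-Cre, active in the endocardial lineage, targets Dicer1. DICER1 cuts microRNA precursors into mature microRNAs. The control library held 70221728 UMIs and 10347 kept cells with a median of 5671 UMIs. The mutant library held 69475632 UMIs and 6190 kept cells with a median of 9490.5 UMIs. There are no replicates, so every value below compares 1 pool with another, and genotype, pool and library preparation coincide. The pools also differed in sex: 93.5% of control cells were female-type and 1 cell was male-type, whereas 42.5% of mutant cells were female-type, 37.1% male-type and 20.5% open.

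Shares of cell classes address which cells the leaflets held. Valve interstitial-like cells, in cluster 0 led by Matn4 and Prss35, cluster 2 by Hist1h1b and Top2a, cluster 5 by Sfrp2 and Angptl7 and cluster 14 by Dpep1 and Fmo2, made up 39.1% (95% interval 38.2 to 40.1) of the control and 25.5% (24.4 to 26.6) of the mutant library. Endothelial-like cells, which formed cluster 7 led by Npr3 and Plvap, made up 7.38% (6.89 to 7.90) and 3.17% (2.74 to 3.63). Clustered without genes that differ between the whole libraries, clusters 7 and 11 fell into 1 endothelial-like cluster with a share of 11.6% and 4.77%, and the valve interstitial-like share was 39.3% and 25.7%. With a class set per cell from its markers the endothelial-like shares lay closer, at 15.4% and 13.4%, and the valve interstitial-like ones were 55.2% and 43.8%. Coronary endothelial-like cells, led by Gpihbp1 and Fabp4, stood at 18.3% and 26.9%, cardiomyocyte-like cells, led by Ttn and Myh7, at 4.35% and 5.62%, and smooth muscle or pericyte-like cells, led by Fabp7 and Rgs5, at 1.84% and 3.72%, or 4.39% and 6.43% when clustered without differing genes. Macrophage-like cells, led by C1qa, stood at 3.27% and 3.54%, and epicardial-like cells, led by Upk3b, at 1.21% and 0.73%. Mast cell-like cells stood at 0.64% and 1.44%, but without differing genes 82.6% of them joined an unnamed cluster led by Trbc2 and Cd7, and the mast cell-like share was 0.20% and 0.08%. Granulocyte-like cells at 0.44% and 0.66%, lymphatic endothelial-like cells at 0.39% and 0.47%, and melanocyte-like cells at 0.45% and 0.32%.

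Within the mutant library the valve interstitial-like share was 31.8% of female-type and 22.5% of male-type cells, a log2 ratio of -0.50, against -0.62 between the libraries. These cells come from different embryos of the same genotype, which also differ in sex. Among female-type control cells the share was 39.7%. The endothelial-like share was 3.54% of female-type and 3.44% of male-type mutant cells, and 7.68% of female-type control cells. Shares depend on dissection, sorting and the depth of each library, and 22.6% of control and 27.9% of mutant cells stayed unnamed. Of the unnamed clusters, cluster 4 held 6.42% and 7.37%, cluster 6 held 5.80% and 7.00%, cluster 9 held 2.83% and 5.25%, cluster 11 held 4.23% and 1.58%, cluster 13 held 1.41% and 3.52%, cluster 15 held 1.01% and 2.04%, cluster 18 held 0.84% and 0.87%, and cluster 23 held 0.09% and 0.31%. Their leading genes were Ccn3 and Sct in cluster 4, Dlk1 and Smoc2 in cluster 6, Cxcl12 and Gja5 in cluster 9, Rian and Meg3 in cluster 13, Plac8 and Lyz2 in cluster 15, Vwf and Procr in cluster 18 and Mcpt8 in cluster 23.

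**Figure D1:**
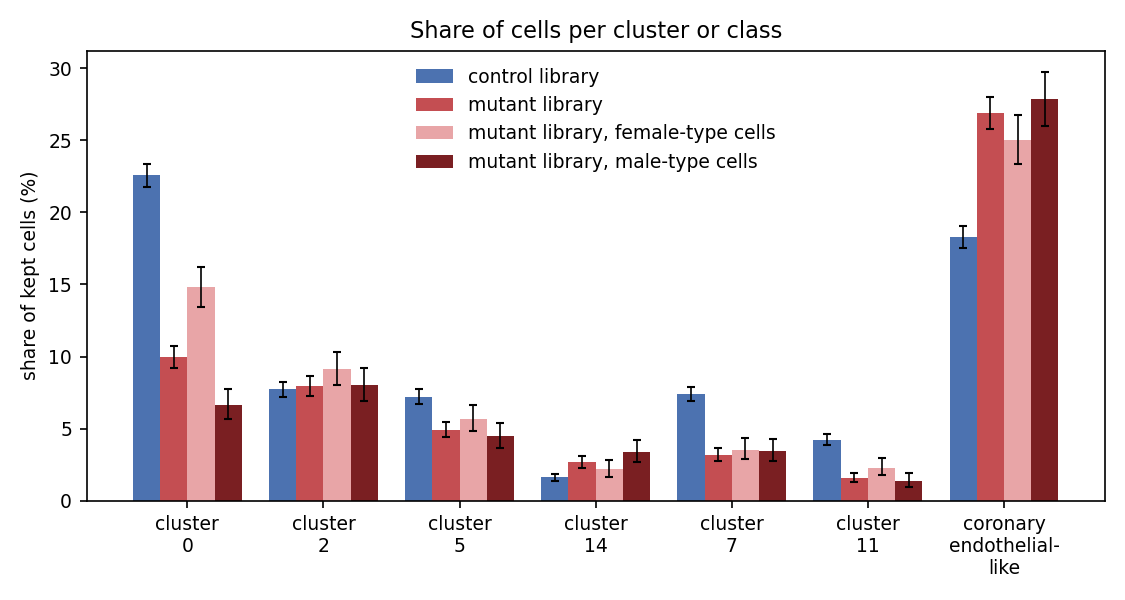
Share of kept cells (percent) in clusters 0, 2, 5, 14, 7 and 11 and in coronary endothelial-like cells. Shares are given for the control library, the mutant library, and the female-type and male-type cells of the mutant library. The 95% Clopper-Pearson intervals cover counting error only. Cluster 0 stands at 22.6% of the control and 9.97% of the mutant library, and cluster 7, the endothelial-like cells, at 7.38% and 3.17%.

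Dicer1 (ENSMUSG00000041415, mm10 chromosome 12, 104687742 to 104751952, minus strand), the targeted gene, was lower in the mutant library in endothelial-like cells, at 41.7 CPM (32.9 to 52.2) against 87.6 (78.6 to 97.4), a log2 ratio of -1.06 (-1.45 to -0.71). In cluster 11, an unnamed cluster with 10 detected endothelial markers and Wnt4, Pthlh and Prox1 among its leading genes, Dicer1 stood at 37.0 against 93.1 CPM, a log2 ratio of -1.32 (-1.82 to -0.87). The ratio was -0.40 (-0.52 to -0.29) in valve interstitial-like cells and -0.34 (-0.48 to -0.20) in coronary endothelial-like cells. It was -0.02 (-0.44 to 0.40) in macrophage-like cells, -0.17 (-0.44 to 0.10) in cardiomyocyte-like cells and -0.06 (-0.53 to 0.42) in smooth muscle or pericyte-like cells. The labels do not name the deleted part of Dicer1, and 3′ tags that lie outside it check nothing about the protein. In 1 random draw of 2000 UMIs per cell the valve interstitial-like ratio was -0.73, and over all possible draws it was -0.42. Nfatc1, the transcription factor after which the Cre is named, had a log2 ratio of 0.38 (0.10 to 0.65) in endothelial-like and -0.20 (-0.32 to -0.09) in valve interstitial-like cells. The labels do not say how the Cre was inserted.

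**Figure D2:**
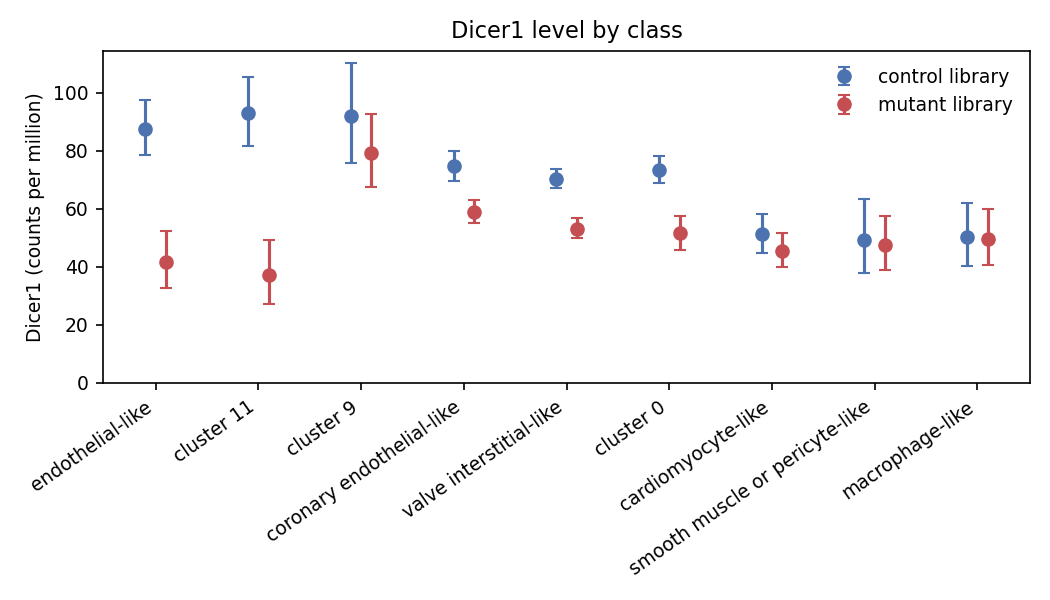
Dicer1 level (CPM) of the control and the mutant library in 6 named classes and in clusters 0, 9 and 11, with exact 95% Poisson intervals that cover counting error only. Endothelial-like cells stand at 87.6 and 41.7, macrophage-like cells at 50.3 and 49.6.

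Endothelial-like cells differed more between the libraries than the other large classes did. Of 3411 genes, 49 were at least 2-fold higher and 22 at least 2-fold lower in the mutant library, from 764 control and 196 mutant cells. Ratios of all genes in this class had a median of 0.103 on the log2 scale, and relative to it 35 were higher and 28 lower. Across 15 alternatives the higher genes numbered 22 to 203 and the lower ones 12 to 114, with the largest numbers at lower level floors. Valve interstitial-like cells had 5 higher and 5 lower of 3330, coronary endothelial-like cells 1 and 2 of 3153, cardiomyocyte-like cells 1 and 3 of 2510, smooth muscle or pericyte-like cells 1 and 0 of 3312, and macrophage-like cells 0 and 6 of 3058, 5 of these 6 erythroid or sex-linked. Mast cell-like cells, with 66 and 89 shallow cells, were not compared. Male-type and female-type cells within the mutant library were at least 2-fold apart for 20 genes in endothelial-like cells (79 and 93 cells). In valve interstitial-like cells (517 and 835 cells) they were for 2.

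Hapln1 (ENSMUSG00000021613, chromosome 13, 89539796 to 89611652, plus strand), which links hyaluronan to proteoglycans, had the highest ratio of the named genes, at 374 against 18.8 CPM in endothelial-like cells, a log2 ratio of 4.30 (3.97 to 4.68). Also higher were Lsr with 2.39 (1.98 to 2.83), the lectin Clec4g 2.30 (1.97 to 2.64), the junction protein Jam2 1.87 (1.56 to 2.18), the integrin Itgav 1.79 (1.46 to 2.12) and the adhesion receptor Adgre5 1.54 (1.26 to 1.82). The glutathione transferase Gsta4 had 1.71 (1.59 to 1.83), Calm2, which encodes calmodulin, 1.59 (1.51 to 1.67), the matrix protease Adamts5 1.61 (1.31 to 1.92), Atp13a3 1.68 (1.31 to 2.07) and the histone gene Hist1h2bc 2.10 (1.79 to 2.41). Wnt4, a secreted signal, had 2.59 (2.28 to 2.91). Lower in the mutant library were Tmem158 with -1.48 (-1.78 to -1.20), S100a16 with -1.41 (-1.68 to -1.16), the transcription factor Cebpd with -1.35 (-1.74 to -0.99), the muscarinic receptor Chrm2 with -1.32 (-1.76 to -0.93), the lipase inhibitor G0s2 with -1.29 (-1.51 to -1.07), Colec11, a leading gene of the smooth muscle or pericyte-like cluster, with -1.19 (0.15 in cluster 11), Cd200 with -1.16, Raph1 with -1.05, the selenium carrier Selenop with -1.04 and Siva1 with -1.03.

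All 12 named higher genes were at least 2-fold higher both between female-type cells and between male-type mutant and female-type control cells, and all 12 lower genes were at least 1.5-fold lower in both. The border between clusters 7 and 11 matters for some of them. In the planned clustering without differing genes, where it is gone, Wnt4 had 0.39, Hapln1 2.32, Lsr 1.54 and Raph1 -0.68. Wnt4 leads cluster 11, and its ratio was 0.39 with cluster 11 added to the class and -0.11 with clusters 9, 11 and 18 added. Hapln1 stood at 376 CPM in control cells of cluster 11, and its ratio was 2.33 and 1.83 with these clusters. With cluster 11 added, 11 of the 12 higher genes stayed at least 2-fold higher and 9 of the 12 lower genes at least 2-fold lower. With clusters 9, 11 and 18 all 12 higher genes but Wnt4 stayed above 0, the lowest being Adamts5 at 0.77 and Calm2 at 0.88. Of the lower genes Raph1 had -0.14 and Cebpd -0.67 with these clusters, Cd200 and S100a16 turned to 0.05 and 0.22, and S100a16 to 0.01 with a class set per cell.

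**Figure D3:**
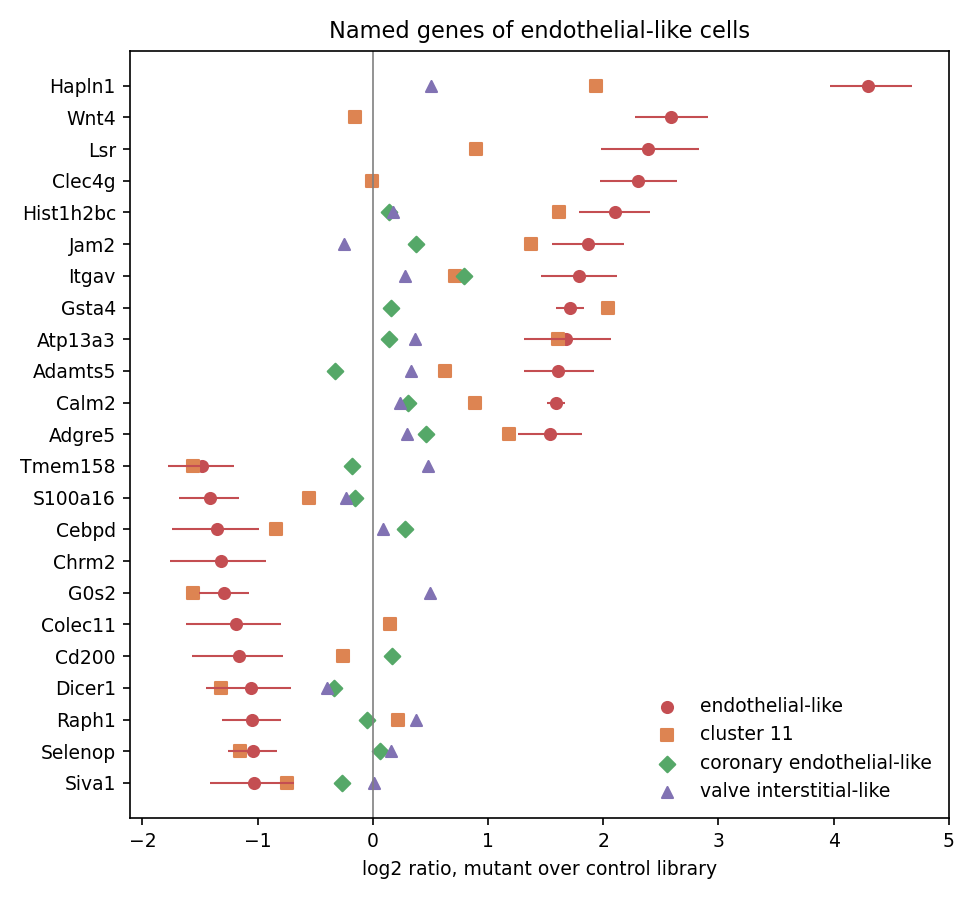
Log2 ratio of mutant over control library for 23 named genes in endothelial-like cells, with 95% intervals for counting error only, and in cluster 11, coronary endothelial-like and valve interstitial-like cells where the mean CPM is at least 10. Hapln1 has the highest ratio at 4.30, and Tmem158 the lowest at -1.48.

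Among the fixed gene lists in endothelial-like cells, let-7 targets were higher in the mutant library, with a median log2 ratio of 0.38 at percentile 99.97. Of 22 measured members 8 were higher and 1, Dicer1, was lower, with Arid3a at 2.83 (60.4 against 8.4 CPM), Arid3b at 1.91, the chromatin protein Hmga2 at 1.74 and Thbs1 at 1.61. Flow-responsive endothelial genes had a median of 0.71 at percentile 100, with 5 of 9 members higher and 1 lower: Thbd 0.98, Klf2 0.96, Timp3 -0.91 and Nos3 0.77. This list was also above the range in coronary endothelial-like cells, with a median of 0.33. Valve and endocardial transcription factors had a median of 0.44, with 7 of 18 higher and 0 lower, led by Klf2 at 0.96, Sox17 at 0.92, Mecom at 0.89 and Gata4 at 0.73. They were also above the range in macrophage-like (0.23) and cardiomyocyte-like cells (0.12), and inside it in coronary endothelial-like cells (0.04). The unfolded protein response had 0.31, with 7 of 20 higher, among them Calr at 0.89, Manf at 0.87, Creld2 at 0.85 and Hspa5 at 0.75. Adhesion and integrin genes had 0.35, with 4 of 14 higher and 1 lower: Itgav 1.79, Vcam1 -1.67, Itgb4 1.60 and Itga1 1.58. Targets of miR-17-92 had 0.30, with 6 of 19 higher and 1 lower, and genes of the G2 and M phases 0.26, with 5 of 23 higher. Collagens were lower, with a median of -0.57 at percentile 0, where 7 of 14 members were lower and 2 higher: Col26a1 -1.60, Col6a2 -1.23, Col6a1 -1.03 and Col14a1 -0.97. Collagens were also below the range in cardiomyocyte-like (-0.39) and coronary endothelial-like cells (-0.12), and inside it in cluster 11 (0.12). Free RNA was not tested for the collagen list. Matn4, Abi3bp, Rspo3 and Col9a3, which lead cluster 0, were also at least 2-fold lower in endothelial-like and coronary endothelial-like cells. Targets of miR-29, a list that shares many collagens, had -0.33 with 5 of 25 lower and 5 higher, and Hapln1 is among the higher ones.

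The dissociation and immediate early list was also above the range in endothelial-like cells, with a median of 0.38 and 6 of 23 members higher, led by Btg2 at 1.21. With each cell thinned to 2000 UMIs in 1 random draw the let-7 median was 0.19 at percentile 69.6, and the miR-29 median turned to 0.02. The let-7 list kept its call in the other 14 alternatives, among them the mean over all possible draws. Flow-responsive genes, the unfolded protein response and the dissociation list kept theirs in all 15. The adhesion list lost its call in 7 of the 15 and miR-17-92 targets in 5. The miR-29 list and the G2 and M list each lost it in 4, apart from reversals, and collagens in 2. The transcription factor median turned to -0.06 with a class set per cell. The median of the G2 and M list turned to -0.23 with clusters 9, 11 and 18 added.

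Inside the range of random lists in endothelial-like cells were proteoglycans (-0.11), elastic fibre (0.24), matrix proteases (-0.02), endothelial-to-mesenchymal transition (0.17), BMP (0.14), TGF-beta (0.14), Notch (0.15), YAP and TEAD targets (0.06), p53 targets (0.22), apoptosis regulators (0.02), S phase (0.20), cyclins and CDKs (0.04), miRNA biogenesis (0.13), miRNA host transcripts (-0.11), imprinted growth genes (-0.11), interferon-stimulated genes (0.33), glycolysis and hypoxia (0.23) and mitochondrially encoded genes (-0.11). The targets of miR-15 and miR-16 (-0.09), miR-21 (0.08), miR-126 (0.01) and miR-143 and miR-145 (0.21) were inside it too. With under 5 measured members, chondrogenic genes had -0.67, tendon genes -0.58, WNT targets -0.36, chemokines -0.55 and pool sex markers 3.23, and no percentile was given.

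Valve interstitial-like cells held small differences. Msx1 (ENSMUSG00000048450, chromosome 5, 37820485 to 37824583, minus strand), a homeobox factor of the cushions, was lower in the mutant library, at 29.0 against 74.4 CPM, a log2 ratio of -1.36 (-1.50 to -1.22). Higher were Col15a1 with 1.17 (1.09 to 1.25), Anxa1 with 1.15 (1.05 to 1.25), the lipoprotein lipase gene Lpl with 1.10 (1.01 to 1.18) and Hmga2, a let-7 target, with 1.07 (0.97 to 1.18). Gpx3 had 0.97, Btg2 0.97 and Ptprb 0.92. Lower were the carbonic anhydrase Car3 with -1.26 (-1.36 to -1.17), Col12a1 with -0.85, St3gal4 with -0.84, Nnat with -0.80, Kazald1 with -0.79, Cdc42ep3 with -0.79 and Ltbp2 with -0.78. The other named genes, Tnxb, Fndc1 and Spon2 among the higher and Matn4, Abi3bp, Rspo3 and Col9a3 among the lower, lead clusters of this class, and Ccn3 and Dlk1 lead clusters 4 and 6. Several lower genes were not particular to the class. In coronary endothelial-like cells 7 of the 12, Car3, Nnat and Ltbp2 among them, were also at least 2-fold lower. In macrophage-like cells 3 were, namely Matn4, Car3 and Nnat. Of the 12 higher genes, 0 and 1 were at least 2-fold higher there. No level floor was applied in these classes. Between female-type cells 11 of the 12 higher and 11 of the 12 lower named genes differed at least 1.5-fold in the same direction. At least 2-fold, 5 and 2 did so. Over all cells of the class, 5 of the 3330 genes were at least 2-fold higher and 5 lower, with 1 erythroid or sex-linked gene among them. Between male-type mutant and female-type control cells the higher and lower named genes numbered 11 and 12 at 1.5-fold, and 10 and 9 at 2-fold.

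The class was made up differently in the 2 libraries: of 4048 control cells 2336 were in cluster 0, 799 in cluster 2, 746 in cluster 5 and 167 in cluster 14, and of 1579 mutant cells 617, 492, 304 and 166. With the same cluster weights in both libraries Msx1 had -0.96, Car3 -0.99, Col15a1 1.02, Anxa1 1.09, Hmga2 1.02 and Btg2 1.18, while Gpx3 had 0.66, Nnat -0.61, Kazald1 -0.54 and Ltbp2 -0.45. With these weights 6 genes were at least 2-fold higher and 1 was lower.

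In valve interstitial-like cells, let-7 targets had a median of 0.24 at percentile 100, and 0.24 with the same cluster weights, with 2 of 19 members, Hmga2 and Thbs1 (0.63), higher and 0 lower. Chondrogenic and osteogenic genes had -0.38 and, with the same weights, -0.18, with 3 of 12 lower, among them Col2a1 at -1.14, though Matn4 and Col9a3 are genes of cluster 0. Valve and endocardial transcription factors had -0.18 and -0.08, with Msx1 at -1.36, Klf2 at 0.97, Prrx2 at -0.74 and Klf4 at 0.67. Collagens had 0.16, which became 0.04 with the same weights, and tendon genes 0.19, which became 0.09. Genes of the G2 and M phases had 0.47, and since they define cluster 2, the same weights (0.01) do not test them, and bear on the S phase and cyclin lists in part. Also above the range were flow-responsive genes (0.31), p53 targets (0.19), S phase (0.31, with the same weights 0.15), cyclins and CDKs (0.37, then 0.19), miR-29 targets (0.16, then 0.08), miR-17-92 targets (0.19, then 0.22), imprinted growth genes (0.34, then 0.14), glycolysis and hypoxia (0.26), the unfolded protein response (0.18), the dissociation list (0.29), mitochondrially encoded genes (0.24) and adhesion (0.28). Several of these were not particular to the class: mitochondrially encoded genes were also above the range in coronary endothelial-like, macrophage-like, cardiomyocyte-like and smooth muscle or pericyte-like cells, glycolysis and hypoxia in the first 3 of these, p53 targets in all but macrophage-like cells, flow-responsive genes and cyclins and CDKs in coronary endothelial-like cells, and the dissociation list and genes of the G2 and M phases in coronary endothelial-like and smooth muscle or pericyte-like cells. Inside the range were proteoglycans (0.01), elastic fibre (-0.02), matrix proteases (-0.03), endothelial-to-mesenchymal transition (0.05), BMP (-0.05), TGF-beta (-0.03), WNT (-0.03), Notch (-0.09), YAP and TEAD targets (0.14), apoptosis regulators (0.07), miRNA biogenesis (0.05), miRNA host transcripts (-0.06) and the targets of miR-15 and miR-16 (0.14), miR-21 (0.09), miR-126 (0.04) and miR-143 and miR-145 (0.13). With the same weights 6 of these lists left the range: TGF-beta (0.15), WNT (0.17), YAP and TEAD (0.26), miR-15 and miR-16 (0.17) and miR-21 (0.16) above it and Notch (-0.15) below. Interferon-stimulated genes (0.22), chemokines (0.58) and pool sex markers (-0.67) had too few members.

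Cells with a UMI of Mki67 or Top2a, genes of dividing cells, made up 21.1% of control and 32.5% of mutant valve interstitial-like cells thinned to 2000 UMIs (29.2% and 45.5% not thinned), with 55 and 26 shallower cells left out. Within cluster 0 the thinned shares were 5.05% (4.19 to 6.02) and 6.33% (4.52 to 8.59), and within the cycling cluster 2 they were 84.1% and 88.5%. Cluster 2, which such genes define, held 7.72% (7.21 to 8.25) of control and 7.95% (7.29 to 8.65) of mutant cells, whereas cluster 0 held 22.6% and 9.97%. Among endothelial-like cells, with 32 and 9 shallower cells left out, they were 3.83% (2.56 to 5.48) and 5.88% (2.97 to 10.3), with overlapping intervals (8.25% and 16.3% of all cells, not thinned). On the same thinned cells, those with 3 UMIs of the G2 and M list made up 52.0% (48.4 to 55.7) and 63.6% (56.3 to 70.5), and those called in G2 or M 7.92% (6.07 to 10.1) and 19.8% (14.3 to 26.2). The control share of 3.83% was the lowest among the classes and clusters measured and is read as a bound on the background from free RNA in the control library. It does not bound the background of the mutant library, where the lowest share was 5.88%. Median depths were 5004 and 9248.5 UMIs in endothelial-like and 5841 and 10806 UMIs in valve interstitial-like cells.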

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

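No paired analysis was possible because each genotype has 1 library. The alternatives with female-type or male-type cells, added clusters, equal cluster weights and the mean over thinning draws were chosen after seeing the data. Across the alternatives, 133 values of the main results stayed within the set limit and 41 moved. The limit is the 95% counting interval of the value, and for a number of genes or lists a factor of 1.5. It is wide for endothelial-like cells with a Mki67 or Top2a UMI, where a difference of 2.06 points became 4.14 without doublet removal and 3.59 at resolution 1.5. Of the list medians, 879 kept their call, 39 lost it, 67 gained one and 5 reversed, and of the named genes 475 values stayed within their counting interval, 226 moved and 4 reversed. Dicer1 was lower in the mutant library under every alternative, between -1.19 and -0.69 in endothelial-like and between -0.73 and -0.27 in valve interstitial-like cells. Intervals reflect counting only, so the spread between embryos stays unknown.

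The cause was not tested for the values that follow, except where lower floors bring in more genes. Endothelial-like shares differed by -1.93 points with a class per cell, -6.87 without differing genes, -5.57 without doublet removal, -5.28 at resolution 1.5 and -3.35 with the stricter filter, and valve interstitial-like shares by -11.43 with a class per cell. In endothelial-like cells 22 genes were higher with a class per cell, 79 after thinning and 75 between male-type mutant and female-type control cells, 12 were lower without doublet removal, and lower floors gave 203 higher and 114 lower. In valve interstitial-like cells the higher genes numbered 1 with a class per cell or with clusters 4 and 6, 13 with per-cell means and over all thinning draws, 10 after thinning, 18 with male-type mutant cells and 24 with lower floors. Lower ones there numbered 3 in female-type cells, 13 with male-type mutant cells, 1 with equal weights and 25 with lower floors. Dicer1 stood at -0.69 in endothelial-like cells with clusters 9, 11 and 18, and in valve interstitial-like cells at -0.73 after thinning and -0.27 with male-type mutant cells.

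Lists above the range in endothelial-like cells numbered 5 after thinning. Lists below it numbered 1 after thinning, without differing genes and with cluster 11, and 5 in female-type cells. In valve interstitial-like cells lists below it numbered 5 with a class per cell, 6 with male-type mutant cells, and 4 without doublet removal, with the stricter filter and with clusters 4 and 6. The difference in cells with a Mki67 or Top2a UMI was 16.32 points without thinning and 6.03 with a class per cell in valve interstitial-like cells, and 8.08, 7.35 and, with 3 UMIs of the G2 and M list, 11.59 in endothelial-like cells. Values that reversed in endothelial-like cells were S100a16 (0.01 with a class per cell, 0.22 with clusters 9, 11 and 18), Wnt4 (-0.11) and Cd200 (0.05) with clusters 9, 11 and 18, the transcription factor list (-0.062 with a class per cell, -0.07 with clusters 9, 11 and 18), the miR-29 list (0.024 after thinning, 0.124 with clusters 9, 11 and 18) and the G2 and M list (-0.234 with clusters 9, 11 and 18).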

Other observations

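Tests on sex of cells, on added clusters, on the let-7 list in other classes and on shares by sex were chosen only after the result was seen, and those on counting error, free RNA, seed sites and lost barcodes before the value they measure was seen. Cluster 11, kept apart from the endothelial-like class by a rule set after its values were seen, also differed between the libraries. It had 88 genes at least 2-fold higher and 31 lower in the mutant library of 3521, from 438 control and 98 mutant cells. Male-type and female-type mutant cells of cluster 11 were at least 2-fold apart for 56 genes. That number rests on only 31 and 60 cells and is not a like comparison. Of the genes measured in both groups, 16 were at least 2-fold higher in cluster 11 and in endothelial-like cells, and 5 were lower in both. Both comparisons use the same 2 libraries. The members named here and the comparison itself were chosen after the values were seen. Flow-responsive genes had a median of 0.84, with 9 of 11 higher, among them Wnt9b at 2.52, Edn1 at 1.33, Klf4 at 1.05 and Dkk1, which rests on few UMIs. TGF-beta targets had 0.57 with 7 of 16 higher, such as Ccn2 at 3.19 and Thbs1 at 1.55, while Postn stood at -1.67, and p53 targets had 0.48 with 9 of 18 higher. YAP and TEAD targets had 0.36, WNT targets 0.38 and let-7 targets 0.38, and the interferon-stimulated list had -0.80 with 5 measured members. The dissociation list had 0.53, with Hspb1 at 1.86, beside all of these.

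Cluster 0, the largest valve interstitial-like cluster, had 11 genes at least 2-fold higher and 2 lower of 3285. Its let-7 list had a median of 0.30, with 4 of 20 higher and 1 lower, miR-17-92 targets 0.28, miR-15 and miR-16 targets 0.26, and Notch genes -0.39. Its dissociation list had 0.53 with 9 of 24 higher. Across classes this list was also above the range in coronary endothelial-like (0.18) and smooth muscle or pericyte-like cells (0.43), and inside it in macrophage-like cells (0.02).

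Endothelial-like cells had 70 genes at least 2-fold apart without erythroid and sex-linked ones, more than the 9 of valve interstitial-like and the 2 of coronary endothelial-like cells. Sex of the pools is argued against as the cause. Between female-type cells 100% of these genes (94.9 to 100) kept 0.5 or more of their log2 ratio, with a median of 1.29 in their direction. Of the higher genes 89.8% (77.8 to 96.6) stood above their level over all mutant cells. This argues against free RNA with the makeup of the kept cells as their only source. The makeup of the free RNA itself was not measured, and the genes were chosen by the same mutant values, which favours this outcome. For the lower genes 61.9% (38.4 to 81.9) stood above their level over all control cells, and too few genes keep free RNA open there. Larger classes drawn down to 764 and 196 cells gave at most 35 genes, in valve interstitial-like cells. Medians were 17 there and 3 in coronary endothelial-like cells, and the draws also hold the differences of these classes between the libraries. Since 35 lies at the limit set beforehand, the share due to drawing few cells cannot be told apart. In the simulation at the UMI totals of endothelial-like cells, 0.0% of 3200 unchanged genes were at least 2-fold apart. This argues against counting of UMIs alone, but the simulation held no spread between cells. A shift of cells between clusters 7 and 11 is argued against as the whole cause, since with cluster 11 added 92.9% (84.1 to 97.6) kept 0.5 or more of their log2 ratio, and 61 genes were higher and 21 lower. Wnt4, Ttn, Sparcl1, Itga9 and Col6a1, named after their values were seen, did not keep it. The spread between embryos and the genotype may each add to the number and stay open.

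The let-7 target list stood above the range in endothelial-like cells and cluster 0. A difference between the whole libraries is argued against, since the list was above the range in 0 of 4 other classes, and in cardiomyocyte-like cells it had -0.21. Loss of microRNA repression predicts that seed sites of many families mark the higher genes, and 2 of the 21 families, let-7 at rank 2 and miR-30 at rank 3 of 16321 heptamers, stood in the top 1% in endothelial-like cells. Coronary endothelial-like cells also had 2 such families, and valve interstitial-like, macrophage-like, cardiomyocyte-like and smooth muscle or pericyte-like cells had 1 each. The miR-126 site, found in 13 genes, was too rare to rank. The number set beforehand was at least 3, so this explanation cannot be told apart from other causes in this class. In cluster 11, 4 families stood in the top 1%, let-7 at rank 2, miR-30 at rank 8, miR-181 at rank 83 and miR-17 at rank 88, and 2 when length, GC content and level were not fitted. In cluster 0 they numbered 4 as well, miR-15, miR-181, miR-214 and miR-199a-3p, and 5 without the fit, while the let-7 site stood at rank 1053 there, or 6.45%. A hypothesis that let-7 and miR-30 activity may be lower in mutant endothelial-like cells would need replicate libraries or small RNA measurements, and miR-30 also stood at rank 3 in coronary endothelial-like cells.

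Clusters 0, 7 and 11 together made up 34.2% of control and 14.7% of mutant cells. Placing every deposited barcode in its closest cluster gave a log2 ratio of -1.45, against -1.34 for kept cells placed the same way. This put 87.7% of kept cells in their own cluster, but was not checked for the removed barcodes. Most barcodes are kept cells, 10347 of 12793 and 6190 of 8250, and barcodes under 500 UMIs are absent. The placement therefore cannot decide whether barcodes lost at the filters are a cause. Male-type over female-type mutant cells gave a log2 ratio of -1.15 in the share of cluster 0, against -1.18 between the libraries. In cluster 11 the values were -0.76 against -1.42. A spread between embryos of the mutant pool predicts such differences, but these embryos also differ in sex, and the 2 cannot be told apart. For cluster 7 a spread between embryos cannot be told apart, with -0.04 against -1.22. There, 2 groups that agree do not measure the spread between single embryos or in the control pool. Among female-type cells alone, cluster 0 held 22.8% of control and 14.8% of mutant cells. Cluster 7 held 7.68% and 3.54% of them, and cluster 11 held 4.36% and 2.28%, so the shares were lower within 1 sex as well. Lost barcodes, dissection, sorting and the genotype stay open for all 3 clusters. The borders of all 3 rest in part on genes that differ between the libraries. Without those genes clusters 7 and 11 fell into the same cluster, and 61.9% of cluster 0 stayed together.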
